A study of Mus musculus with 8 samples.

How the data were processed

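RNA from cultured mouse pancreatic cancer cells was sequenced in 8 libraries. Per the labels' protocols, 2 single-cell clones, HC800-A8-1 and HC569-A8-18, were grown from 2D cultures of murine pancreatic tumors (mixed 129/B6 strain), treated with doxycycline (1 mg/ml, as the labels print it) or vehicle for 7 days, and lysed in TRIzol. The labels' protocols name a TruSeq Stranded RNA library kit and, to remove ribosomal RNA, Ribo-Zero Gold. Per the submitters' processing notes, reads were aligned with STAR 2.5.4a and assigned to genes with featureCounts 1.6.3. The same notes name DESeq2 1.22.2 and the human genome build GRCh38, whereas all 53801 identifiers of the deposited table are mouse Ensembl genes. The strand setting, annotation release and filters are not given in the sources used here. The deposited values are whole-number counts per gene and library, with no scaling.

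Identifiers were matched to symbols and GRCm38 coordinates in GENCODE M21, which covered 53620 of them. 93 symbols were shared by more than 1 identifier, and 0 lines of the table named no gene. Library sizes were scaled with TMM factors, and genes were kept by filterByExpr with the 4 groups (clone and treatment, 2 libraries each), which left 15571. CPM are counts scaled to a fixed library size, as given by edgeR's cpm function with the scaled library sizes.

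Tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, 2-sided) with Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p under 0.05. The standard error (SE) of a log2 fold change is its absolute value over the square root of F. The overall comparison set 4 doxycycline (DOX) libraries against 4 control libraries with the clone as a covariate (residual df 5). A fit with 1 mean per group (residual df 4) gave the DOX effect within each clone, the difference of that effect between the clones (HC569-A8-18 minus HC800-A8-1), and the difference between the control libraries of the clones. With 1 clone per tumor line, a difference between clones is a difference between 2 clones. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list, adjusted over the 24 lists with at least 3 tested members. The 26 lists, drawn from general knowledge, the samples, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined.

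The rule named Hnf4a and, in each direction, the 12 genes with the largest log2 fold change among those with adjusted p under 0.05, a mean of at least 2 CPM, the same direction in all 4 pairs of clone and replicate number, and a symbol other than a predicted gene model. It further named up to 4 passing members of each list with the largest change (the 2 with the highest CPM where none passed), Six1, Six4, Cdh1, Vim and Mki67 in any case, 6 genes in each direction for the difference between clones, and 4 in each direction for the control libraries. For genes with 0 counts in a group the ratio is given as at least N-fold, against a floor of 3 counts over that group. For 1 to 3 counts it is given with a 95% counting interval. These bounds and intervals, and the Wilson intervals of shares, cover counting error only, and reads copied by PCR cannot be recognised without molecular barcodes. The p values measure only the spread between these libraries, and the labels do not say whether replicates were separate cultures.

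Library titles carry the number 15145 (replicate 1 of HC800-A8-1, control and DOX) or 15783 (the other 6 libraries). What the number marks is not stated, so tests were repeated with a title-number term (residual df 3 in the group fit) and within the 15783 libraries. Because 15145 occurs only in HC800-A8-1, the term is estimated from the replicates of that clone alone. It cannot be told apart from the gap between those replicates. Other alternatives were DESeq2 1.42.0, no filter, a filter of 1 CPM in 4 libraries, other scaling factors, no clone term, the mean of the clone effects, each clone alone, a block for the replicate number, and leaving out each library in turn. The title-number term was added after the libraries had been inspected. The difference between clones gave no passing gene, so the genes named for it come from the fit with that term. The pipeline was tested on simulated data built from these libraries. The comparison over both clones recovered 25%, 85% and 100% of genes changed by log2 1, 2 and 4, with 8 false calls among 136. The difference between clones recovered 0%, 10% and 82.5%, with 5 false calls among 46. The simulated data held no shift between title numbers, and the fit with the title-number term was not run on them. Figures were drawn from the result tables, and no per-sample column was left unused.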

Results

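The 8 libraries of HC800-A8-1 and HC569-A8-18 held 2 control and 2 DOX libraries per clone. Total counts were 20656123 and 22379575 (HC800-A8-1 control), 17296612 and 22456130 (HC800-A8-1 DOX), 24026857 and 21324666 (HC569-A8-18 control), and 21613440 and 19164929 (HC569-A8-18 DOX). In a principal component analysis of log2 CPM, the first component (56.3% of variance) separated the clones, the second (22.7%) separated DOX from control in both clones, and the third (12.3%) separated replicate 1 from replicate 2 of HC800-A8-1. The small nuclear RNA gene Rn7sk held 386885 and 241039 counts in the HC800-A8-1 replicate 1 libraries, which alone carry title number 15145, and 6 to 87 counts in the other libraries. The variance between replicates, as chi-square per degree of freedom, was 269 and 189.7 in HC800-A8-1 (control and DOX) and 9.36 and 2.84 in HC569-A8-18.

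Hnf4a, the restored gene, was read first to compare each library with its label. Hnf4a encodes a nuclear receptor that drives liver and intestinal gene programmes (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910, GRCm38). It stood at 18.1 and 56.4 CPM in the HC800-A8-1 control libraries and 2082 and 2555 CPM with DOX, and at 134 and 141 CPM in the HC569-A8-18 control libraries and 1117 and 1053 CPM with DOX. Over both clones Hnf4a rose from 87.5 ± 60.2 to 1702 ± 738 CPM (mean ± SD, n = 4 per arm), a log2 fold change of 4.46 (SE 0.76, adjusted p = 0.0157, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Within each clone both DOX libraries stood above both control libraries, the order their labels give. No control library was free of Hnf4a transcript. Hnf4a rose by 4.52 (SE 0.76, adjusted p = 0.00972) with the title-number term and by 3.76 (SE 0.58, adjusted p = 0.00971) in the 15783 libraries. Without HC800-A8-1 control replicate 2 the Hnf4a change was 4.19 (adjusted p = 0.0533), and with no filter on low counts 4.46 (adjusted p = 0.0645). The counts do not separate transcripts of the introduced gene from those of the cells' own gene.

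The overall comparison asked which genes differ between DOX and control cells of the same clones, that is, at high and at low levels of Hnf4a transcript. Muc13, a transmembrane mucin of gut epithelium (ENSMUSG00000022824, chromosome 16, 33794037 to 33819934, GRCm38), rose from 0.0466 ± 0.0547 to 684 ± 324 CPM (mean ± SD, n = 4 per arm). Its log2 fold change was 13.66 (SE 0.53, adjusted p = 8.56e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Aldob, the aldolase of liver fructose metabolism (ENSMUSG00000028307, chromosome 4, 49535995 to 49549546, GRCm38), went from 1 count in the control libraries to 112 ± 31.5 CPM, a ratio of 9812 (95% counting interval 1761 to 387614, adjusted p = 5.95e-05). Uroc1, the urocanase of histidine breakdown, rose 4805-fold (1330 to 39680.5, adjusted p = 0.000431). Genes with 0 counts in all control libraries rose at least 2087-fold (Minar1, adjusted p = 0.000941), 1747-fold (the calcium-binding protein gene Cabp2, 0.00302), 869.7-fold (Pck1 of gluconeogenesis, 0.0214), 848-fold (the phosphatase inhibitor gene Ppp1r14d, 0.00123) and 847-fold (Hgd of tyrosine breakdown, 0.0106). On the same measure Slc27a2 of fatty acid uptake rose 811-fold (0.0126), with 808-fold (the apolipoprotein gene Apoa4, 0.00901), 697-fold (the lipid droplet methyltransferase gene Mettl7b, 0.00106) and 671-fold (Clca4b, 0.00371).

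Among genes lower with DOX, Mmp3, a matrix metalloproteinase, fell (log2 −6.26, SE 0.49, adjusted p = 0.00106), from 20.96 ± 27.7 to 0.26 ± 0.30 CPM (mean ± SD, n = 4 per arm). Its neighbour Mmp10 went from 505 counts to 1 count, a ratio of 0.00218 (95% counting interval 5.52e-05 to 0.0122, adjusted p = 0.0196). The arginine deiminase gene Padi4 fell (log2 −5.03, SE 0.79, adjusted p = 0.0126), as did the protocadherin gene Pcdh9 (−4.79, SE 0.99, 0.0297) and the acyl-CoA synthetase gene Acsl6 (−4.68, SE 0.37, 0.00105). Ly6c1 (−4.61, SE 0.63, 0.0075), the histone deacetylase gene Hdac9 (−4.37, SE 0.41, 0.00206) and Fam167a (−4.24, SE 0.60, 0.0084) were lower as well. The protease gene Mcpt8 stood at 32.9 ± 19.9 CPM in control and 2.68 ± 2.60 CPM in DOX libraries (adjusted p = 0.00527). The receptor kinase gene Flt3 (−4.16, SE 0.78, 0.021), the GABA receptor subunit gene Gabrp (−4.09, SE 0.53, 0.0064) and the teneurin gene Tenm4 (−4.03, SE 0.42, 0.00298) fell by similar amounts. In HC569-A8-18 Mmp3, Mmp10, Acsl6 and Flt3 were near 0 without DOX (5, 3, 4 and 10 control counts against 0, 0, 0 and 2 with DOX), with 95% counting intervals of the ratio up to 1.26, 2.80, 1.75 and 1.09, so their fall rests on HC800-A8-1. All genes named by this rule passed with the title-number term and within the 15783 libraries. Pck1 did not pass without HC800-A8-1 control replicate 2 or either HC569-A8-18 DOX library (adjusted p = 0.0523 to 0.0635), Slc27a2 without HC569-A8-18 DOX replicate 1 (0.0515) and Padi4 without HC569-A8-18 DOX replicate 2 (0.0514). Mmp10 passed only in full and without an HC800-A8-1 control library (otherwise 0.0513 to 0.161). Pcdh9 (0.0657 to 0.115) and Flt3 (0.0521 to 0.0833) each lost the call without either HC800-A8-1 DOX library, HC569-A8-18 control replicate 1 or DOX replicate 1. Pcdh9 also lost it without HC569-A8-18 DOX replicate 2, and Flt3 without HC569-A8-18 control replicate 2.

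Of 15571 genes tested, 858 were higher and 375 lower with DOX, and 675 and 269 of these changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). Hnf4a itself, Muc13 and 81 genes at 0 in all control libraries were among the higher genes, and 1 lower gene was at 0 in all DOX libraries. 833 of the higher and 360 of the lower genes moved the same way in all 4 pairs. The genes were called on these same libraries, so this count describes the calls and adds no support. With the title-number term 1955 genes were higher and 1556 lower, including all 1233 of the first calls in the same direction, and in the 15783 libraries 2140 and 1813. The share of higher genes among the calls was 69.6%, and 55.7% with the term. Leaving out 1 HC569-A8-18 library left 291 to 362 higher and 103 to 154 lower genes, and leaving out HC800-A8-1 DOX replicate 1, control replicate 2 or DOX replicate 2 left 224, 224 and 206 lower genes.

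**Figure D1:**
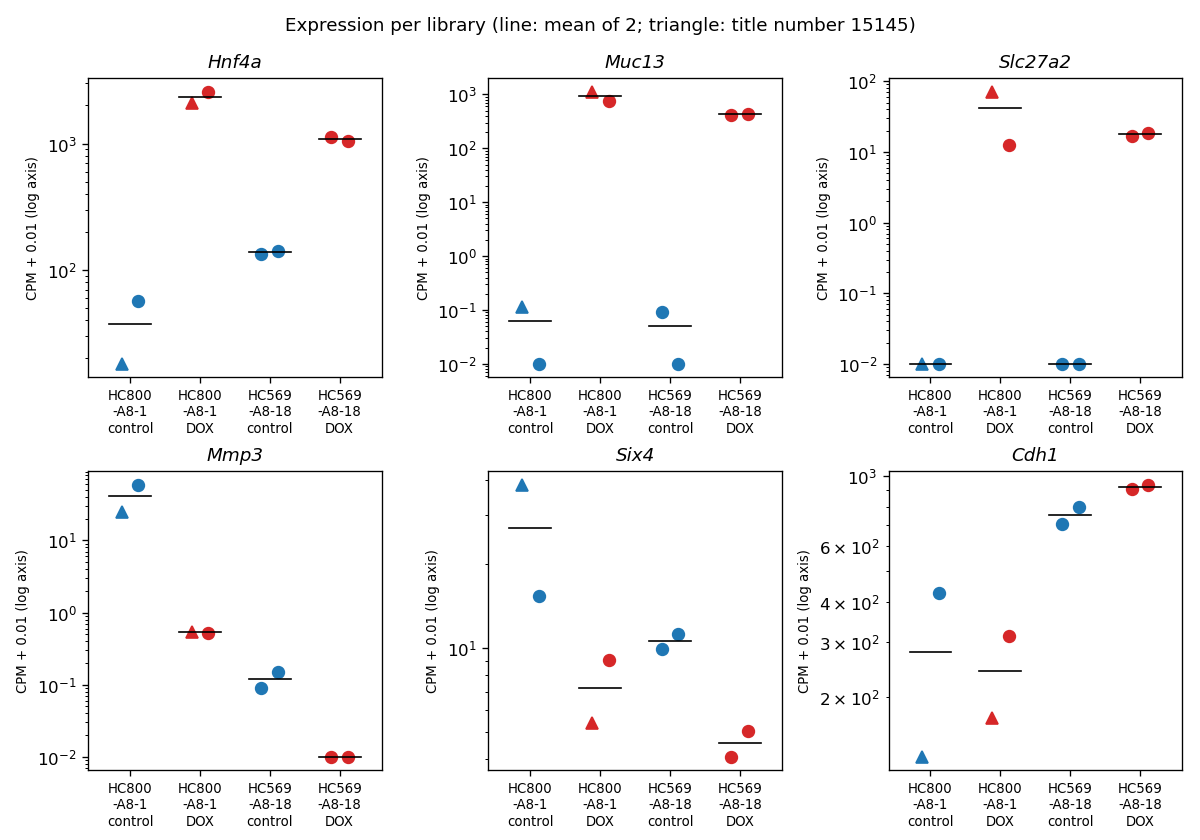
CPM of Hnf4a, Muc13, Slc27a2, Mmp3, Six4 and Cdh1 in each library (logarithmic axis; line, mean of 2 libraries; triangles, libraries with title number 15145).

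Gene lists asked which programmes moved with DOX. Of 32 tested HNF4A targets of liver and gut, which serve lipid export and nutrient metabolism, 19 rose and 0 fell (23 and 0 adjusted over the list alone). Their median log2 fold change was 6.21, or 4.49 with genes at 0 in control set to their bound. The list rose with an adjusted p = 1.49e-39 in limma's camera test (0.00742 with an estimated correlation). Apob, the structural protein gene of lipoproteins, rose from 0.28 ± 0.19 to 1391 ± 1292 CPM (mean ± SD, n = 4 per arm), by log2 11.89 (SE 0.69, adjusted p = 0.000431), beside Aldob, Pck1 and Apoa4. Of 29 genes of xenobiotic metabolism and transport, 21 rose and 0 fell (24 and 0 over the list alone, median 3.17), with an adjusted p = 8.68e-33 (0.0391 with an estimated correlation). Among them the carboxylesterase gene Ces2a rose 1499-fold (95% counting interval 415 to 12387, adjusted p = 0.00173), and the sulfotransferase gene Sult1b1 1322-fold (237 to 52248, 0.000431). The cytochrome P450 gene Cyp4f14 rose 1166-fold (322 to 9636, 0.00271) and Cyp2c65 at least 280.2-fold (0.0142, and 0.0628 to 0.0632 without either HC569-A8-18 DOX library). Which member of such a gene family a read came from is uncertain. With the title-number term 23 targets and 27 xenobiotic genes rose (adjusted p = 0.0381 and 0.0227 with an estimated correlation).

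Fatty acid oxidation and uptake, the burning of fat in mitochondria and peroxisomes, counted 9 higher and 0 lower of 26 genes (20 and 0 adjusted over the list alone, median 0.77). The camera adjusted p was 1.12e-11 (0.0903 with an estimated correlation). Beside Slc27a2, the fatty acid binding protein gene Fabp1 rose 164-fold (95% counting interval 55.9 to 800.1, adjusted p = 0.00561), Ehhadh by log2 3.32 (SE 0.55, 0.014) and Hadh by 1.36 (SE 0.25, 0.0203). Ehhadh did not pass without HC569-A8-18 control replicate 2 (0.0530), nor Hadh without any 1 of the HC569-A8-18 libraries (0.0623 to 0.0665). Of 19 coagulation and complement genes, proteins the liver secretes, 6 rose and 0 fell (7 and 0 over the list alone, median 0.85), with an adjusted p = 7.16e-05 (0.169 with an estimated correlation). Fibrinogen gene Fga rose by log2 6.44 (SE 1.04, adjusted p = 0.0137), Itih4 at least 40.5-fold (0.0157), Serpind1 at least 24.3-fold (0.0212) and F10 120.3-fold (21.1 to 4793, 0.0327), with F10 at 0 in both arms of HC800-A8-1. Fga lost its call without HC569-A8-18 control replicate 1 (0.0544) or HC800-A8-1 control replicate 2 (0.0575). So did Itih4 without HC800-A8-1 DOX replicate 2 or either HC569-A8-18 DOX library (0.0546 to 0.0682) and Serpind1 without HC800-A8-1 DOX replicate 1 or any HC569-A8-18 library (0.05002 to 0.0919). F10 lost it without any HC569-A8-18 library (0.0888 to 0.151). The cholesterol synthesis list did not pass over both clones (median 0.16, adjusted p = 0.474, and 0.0300 without HC800-A8-1 DOX replicate 2). Of 24 genes 0 were higher and 1 lower, also over the list alone (5 and 1 unadjusted, 3 and 1 with DESeq2 and with the title-number term). In HC569-A8-18 21 of the 24 cholesterol genes lay above 0 (median 0.45, adjusted p = 0.0470, 0.810 with an estimated correlation), and in HC800-A8-1 9 did (median −0.10, adjusted p = 0.741). The lower gene, Pcsk9, which lowers LDL receptors, fell (log2 −3.07, SE 0.66, adjusted p = 0.0342), from 63.6 to 3.17 CPM in HC800-A8-1 and from 2.24 to 0.774 CPM in HC569-A8-18. With a library left out Pcsk9 passed only when that was HC800-A8-1 control replicate 1 (otherwise 0.0588 to 0.116). The glycolysis and hypoxia list did not pass (25 genes, 0 called, also over the list alone, with edgeR; 1 and 0 unadjusted and with DESeq2; 2 and 2 with the title-number term; median −0.11, adjusted p = 0.855). Pkm stood at −0.12 (SE 0.22, 0.801) and Gapdh at 0.21 (SE 0.19, 0.564).

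The lists of pancreatic cancer subtypes asked whether the cells took on a classical or basal-like profile. Of 19 genes of the classical subtype, the more gut-like class of pancreatic tumors, 7 rose and 0 fell (11 and 3 adjusted over the list alone, 10 and 2 with the title-number term, median 1.55). The camera adjusted p was 9.63e-09 (0.0391 with an estimated correlation, and 0.0725 with the title-number term as well). Krt20, a keratin of gut epithelium, rose by log2 6.60 (SE 0.50, adjusted p = 0.000941) and Clrn3 at least 223-fold (0.00331). The trefoil factor gene Tff3 rose 121-fold (95% counting interval 33.2 to 1008, 0.00159) and the lysozyme gene Lyz2 at least 42.7-fold (0.0122, and 0.0609 to 0.0645 without either HC569-A8-18 DOX library). Tff3 had 10 DOX counts in HC800-A8-1 and 210 in HC569-A8-18. Other classical genes went down: Ctse and Tff2 were lower with DESeq2, and Ctse was lower in HC800-A8-1 with edgeR. Of 15 basal-like genes 1 rose and 1 fell (2 and 3 over the list alone, 3 and 2 with the title-number term), and the list did not pass over both clones (median −0.16, adjusted p = 0.194). Within clones the basal-like list was lower in HC800-A8-1 (0 higher and 3 lower, median −1.44, adjusted p = 0.00437, 0.252 with an estimated correlation) and not in HC569-A8-18 (0 and 1, median 0.00132, adjusted p = 0.524). Lemd1 fell to 3 counts, a ratio of 0.0228 (0.00465 to 0.0680, adjusted p = 0.00271). Krt5, a basal keratin, rose by log2 2.89 (SE 0.61, edgeR adjusted p = 0.0312) on 7 control and 49 DOX counts and in 3 of 4 pairs. HC800-A8-1 held 0 control counts and 1 DOX count of Krt5, so its rise rests on HC569-A8-18 (7 and 48 counts). Krt5 did not pass without any HC569-A8-18 library or without replicate 2 of either HC800-A8-1 arm (0.0574 to 0.177).

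Of 25 genes of epithelial junctions and the brush border, the microvilli of absorptive cells, 8 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.49). The camera adjusted p was 4.36e-10 (0.0391 with an estimated correlation, and 0.0933 with the title-number term as well). Cdhr2, a protocadherin that links microvilli, rose from 0.223 to 487 ± 143 CPM, by log2 11.23 (SE 0.75, adjusted p = 0.000594), and its partner Cdhr5 at least 401-fold (0.0107). The villin gene Vil1 rose by log2 9.48 (SE 0.75, 0.00108) and Eps8l3 by 6.38 (SE 0.57, 0.00172). Cdh1, which encodes E-cadherin, did not pass (0.05, SE 0.37, edgeR adjusted p = 0.955). Its pooled counts gave a DOX to control ratio of 0.866 in HC800-A8-1 and 1.24 in HC569-A8-18. None of 24 mesenchymal genes passed with edgeR (0 higher and 0 lower, also over the list alone; 1 and 5 unadjusted; 0 and 4 with DESeq2; 0 and 5 with the title-number term). Vim, the vimentin gene, stood at −0.55 (SE 0.21, adjusted p = 0.17, and −0.28 with 0.0487 within the 15783 libraries) and Fn1 at −0.61 (SE 0.30, 0.261). Taken whole, the list was lower (median −0.58, adjusted p = 0.0393, 0.602 with an estimated correlation), but not in the 15783 libraries (0.140) or without HC800-A8-1 control replicate 1 (0.0933), DOX replicate 1 (0.153) or control replicate 2 (0.130). Within clones the mesenchymal list was lower in HC800-A8-1 (median −0.95, adjusted p = 0.000720, 0.343 with an estimated correlation) and not in HC569-A8-18 (12 of 24 above 0, median −0.02, adjusted p = 0.867).

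Developmental regulators asked whether cell identity factors moved. Of 6 factors of the Six4, Eya2 and Dach1 families, embryonic regulators that act together, 0 rose and 1 fell (0 and 4 adjusted over the list alone, and 0 and 4 with the title-number term, median −1.31). The camera adjusted p was 0.0122 (0.291 with an estimated correlation). Within clones the adjusted p was 0.0618 in HC800-A8-1 and 0.00880 in HC569-A8-18 (0.347 with an estimated correlation). Six4 fell (log2 −1.56, SE 0.35, adjusted p = 0.0389), from 18.8 ± 13.3 to 5.89 ± 2.19 CPM (n = 4 per arm). It lost the call when any library but an HC800-A8-1 control was left out (0.0862 to 0.115). Six1 stood at −1.36 (SE 0.46, adjusted p = 0.119, and 0.0303 with the title-number term). Among 21 endodermal transcription factors, which set gut, liver and pancreas identity, 3 rose and 1 fell, also over the list alone (4 and 4 with the title-number term). Hnf1a, a partner of HNF4A, rose by log2 6.22 (SE 0.73, adjusted p = 0.00484), Creb3l3 by 4.68 (SE 0.78, 0.0146) and Klf4 by 0.73 (SE 0.16, 0.0373), and Foxa3 fell (−1.63, SE 0.35, 0.0322). The endodermal median was −0.23, the mean 0.31 and the test direction up (adjusted p = 0.848). Creb3l3 did not pass without HC569-A8-18 control replicate 1 (0.0710) or DOX replicate 1 (0.0506). Foxa3 passed only in full and without HC800-A8-1 control replicate 1 (otherwise 0.0605 to 0.0981), and Klf4 only in full and without HC569-A8-18 control replicate 2 (otherwise 0.0513 to 0.126). None of 14 mesodermal and neural development factors passed (0 and 0 with edgeR; 0 and 2 over the list alone; 0 and 6 unadjusted; 0 and 4 with DESeq2 and with the title-number term). Of these factors 13 lay below 0, and the list was lower (median −1.08, adjusted p = 0.00343, 0.169 with an estimated correlation). Nes stood at −1.21 (SE 0.51, adjusted p = 0.197) and Eya1 at −1.26 (SE 0.25, 0.0596), with 0.031 for Eya1 without HC800-A8-1 control replicate 1. Both passed with the title-number term (0.0285 and 0.0149), and Eya1 and Six1 within the 15783 libraries (0.00490 and 0.0143). Eya1 had 0 counts in both arms of HC800-A8-1, so its change rests on HC569-A8-18.

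Proliferation and stress lists asked whether growth changed. All 26 cell cycle genes lay below 0, with 0 passing (edgeR, also over the list alone; 0 higher and 11 lower unadjusted; 0 and 6 with DESeq2; 0 and 8 with the title-number term). The list was lower (median −0.39, camera adjusted p = 0.000428, 0.475 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at −0.76 (SE 0.24, adjusted p = 0.107, and 0.0356 without HC800-A8-1 control replicate 1) and Mki67 at −0.32 (SE 0.25, 0.489). Top2a passed with the title-number term (0.0476), and both were lower within the 15783 libraries (−0.45 and −0.22, adjusted p = 0.00800 and 0.0348). The 24 genes of ATF4 and the integrated stress response, which answer amino acid shortage, had 0 passing (also over the list alone; 0 and 5 unadjusted; 0 and 3 with DESeq2 and with the title-number term). They were lower as a list (median −0.67, adjusted p = 0.0290, 0.780 with an estimated correlation). In HC800-A8-1 1 of the 24 lay above 0 (median −1.10, adjusted p = 0.000195, 0.587 with an estimated correlation), and in HC569-A8-18 13 did (median 0.04, adjusted p = 0.966). Atf4 stood at −0.59 (SE 0.36, 0.366) and Psat1 at −0.64 (SE 0.27, 0.191). The ATF4 list did not pass in the 15783 libraries (0.69998) or without HC800-A8-1 control replicate 1 (0.927), DOX replicate 1 (0.0759) or DOX replicate 2 (0.0926). Of 24 interferon response genes 1 rose and 0 fell, also over the list alone (5 and 1 with the title-number term): the viral RNA sensor gene Ddx58 rose by log2 1.71 (SE 0.28, adjusted p = 0.0146). Ddx58 did not pass without HC569-A8-18 control replicate 2 or either DOX library of that clone (0.0509 to 0.0575). The interferon list did not pass (median 0.22, adjusted p = 0.0787), but did without HC800-A8-1 control replicate 2 (0.000185), DOX replicate 1 (0.0323) or HC569-A8-18 DOX replicate 1 (0.0465), with no filter on low counts (0.0228), with the 1 CPM filter (0.0413) and with no clone term (0.0364).

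The next lists asked whether genes of mitochondria, ribosomes and chromatin moved. All 29 nuclear-encoded respiratory chain genes lay above 0, with 0 passing (edgeR, also over the list alone; 11 and 0 unadjusted; 4 and 0 with DESeq2; 9 and 0 with the title-number term). The list was higher (median 0.22, camera adjusted p = 0.0254, 0.545 with an estimated correlation). Atp5b stood at 0.03 (SE 0.11, adjusted p = 0.905) and Atp5a1 at 0.18 (SE 0.13, 0.464). All 13 mitochondrially encoded proteins of the list had a symbol in the data, but the filter on low counts kept only 7. Of these 0 passed (0 also over the list alone, unadjusted and with DESeq2). Their median was 0.21 (camera adjusted p = 0.848). Transcripts of mt-Co1 stood at 0.16 (SE 0.25, 0.762) and mt-Cytb at 0.29 (SE 0.98, 0.901). Of 35 cytosolic ribosomal proteins 33 lay below 0 with 0 passing (0 also over the list alone, unadjusted and with DESeq2, 1 lower with the title-number term). The list was lower (median −0.19, adjusted p = 0.0366, 0.780 with an estimated correlation), but not without HC800-A8-1 control replicate 1 (0.301) or DOX replicate 2 (0.173). The ribosomal list passed as lower in HC800-A8-1 (camera adjusted p = 0.0168, 0.855 with an estimated correlation) and did not pass in HC569-A8-18 (0.204). The difference between clones did not pass in the same fit (0.183, 0.912 with an estimated correlation). Rps2 stood at −0.15 (SE 0.12, 0.515) and Rpl4 at −0.20 (SE 0.13, 0.377). With the title-number term 4 of the 7 mitochondrially encoded genes and 11 of the 29 respiratory chain genes were higher, and 17 of the 35 ribosomal genes lower, in HC800-A8-1, against 0, 1 and 0 in HC569-A8-18. Among all genes that fit called 5792 in HC800-A8-1 and 2162 in HC569-A8-18. Its difference between clones did not pass for the mitochondrially encoded (camera adjusted p = 0.0924) or respiratory chain list (0.502). For the ribosomal list it passed (0.0139, but 0.722 with an estimated correlation). The histone list, mostly replication-dependent genes whose transcripts lack a poly(A) tail, had 0 of 20 passing (also over the list alone; 0 and 1 unadjusted; 0 and 0 with DESeq2; 0 and 3 with the title-number term; median −0.51, adjusted p = 0.583). The linker histone gene H1f0, which is not replication-dependent, stood at −0.52 (SE 0.20, 0.157, and 0.0434 with the title-number term) and Hist1h1c at −0.52 (SE 0.69, 0.715).

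Cell type marker lists asked whether pancreatic duct identity or traces of other cells moved. Of 14 duct markers 1 rose and 1 fell, also over the list alone (1 and 3 with the title-number term, adjusted p = 0.229). The osteopontin gene Spp1 fell (log2 −2.29, SE 0.33, adjusted p = 0.0094), from 7813 ± 5096 to 1374 ± 719 CPM. Tspan8, which is also in the classical list, rose by 1.43 (SE 0.13, 0.00183), from 255 ± 139 to 657 ± 282 CPM (n = 4 per arm). Of 7 macrophage and leukocyte markers 1 rose and 0 fell (3 and 0 over the list alone, 2 and 1 with the title-number term, adjusted p = 0.194). In HC569-A8-18 the macrophage and leukocyte list was higher (5 of 7 above 0, median 0.91, adjusted p = 0.0356, 0.278 with an estimated correlation). The macrophage receptor gene Csf1r rose 53.5-fold (95% counting interval 14.4 to 448, adjusted p = 0.0283). Csf1r did not pass without any HC569-A8-18 library or HC800-A8-1 DOX replicate 2 (0.0604 to 0.117). Of 8 endothelial markers 0 rose and 1 fell, also over the list alone (median −0.47, mean 0.03, test direction down, adjusted p = 0.345). The growth factor receptor gene Flt1 fell (log2 −1.52, SE 0.24, 0.0123, and 0.0617 without HC569-A8-18 DOX replicate 2). None of 7 fibroblast markers passed (0 also over the list alone, unadjusted and with DESeq2; adjusted p = 0.855), with Pdpn at 0.52 (SE 0.24, 0.273) and Fbln1 at 0.43 (SE 0.59, 0.723). Only 2 acinar genes, Cela1 (−0.87, SE 0.57, 0.407, and 0.0428 within the 15783 libraries) and Bhlha15 (−0.07, SE 0.53, 0.96), and 1 endocrine gene, Syp (−0.09, SE 0.71, 0.963), were expressed enough to test, with 0 passing, 0 unadjusted and 0 with DESeq2.

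**Figure D2:**
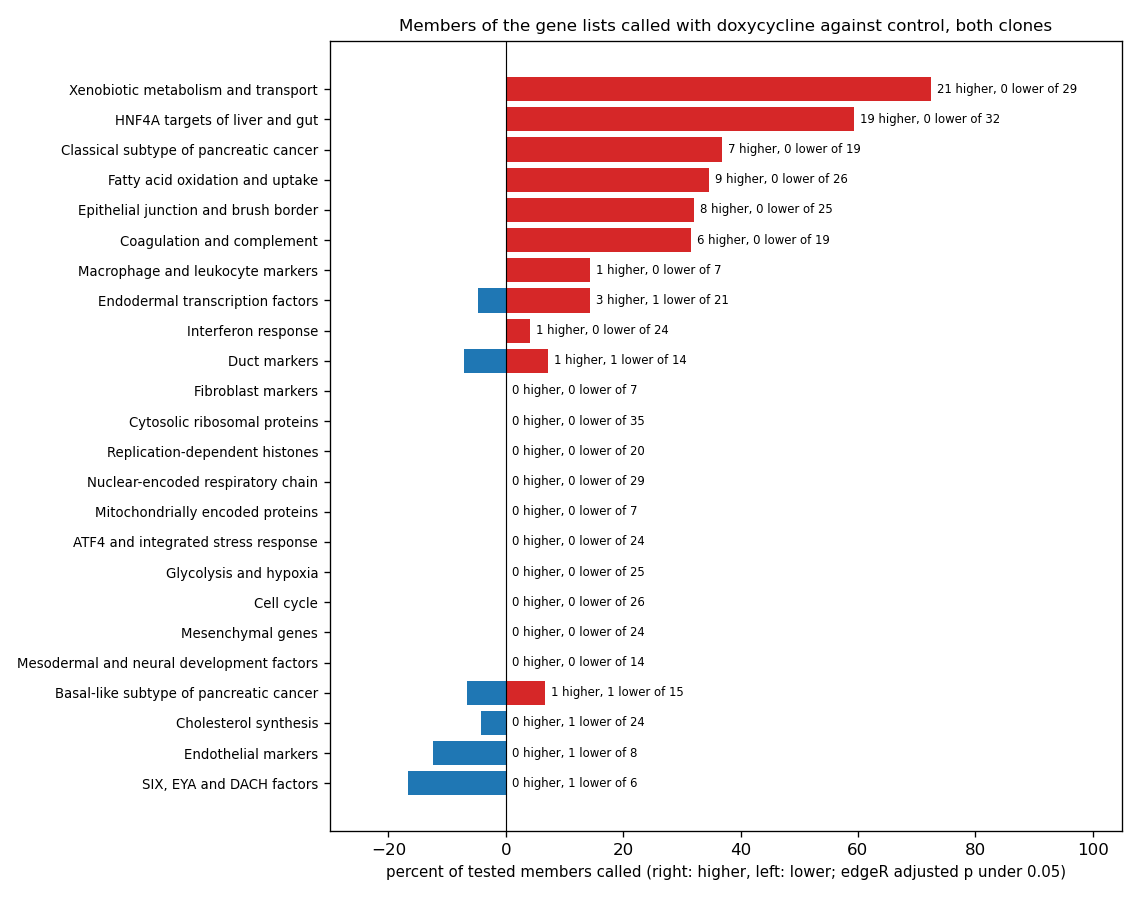
Share of tested members of each gene list that were higher (right) or lower (left) with DOX, edgeR adjusted p under 0.05 over all genes.

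The comparisons within each clone asked whether both clones responded. Hnf4a rose by log2 5.96 (SE 0.59, adjusted p = 0.00689) in HC800-A8-1. It stood at 2.98 (SE 0.52, adjusted p = 0.0553) in HC569-A8-18, where it passed with the title-number term (2.98, SE 0.29, adjusted p = 0.00152; edgeR quasi-likelihood test, Benjamini-Hochberg). In HC800-A8-1 16 HNF4A targets rose and 1, the lipase gene Lipc, fell, and in HC569-A8-18 11 rose and 0 fell (adjusted p = 4.24e-16 and 2.79e-31, or 0.138 and 0.0932 with an estimated correlation). Xenobiotic genes counted 13 and 10 higher, brush border and junction genes 12 and 4, and fatty acid oxidation genes 14 and 0, in the order of the clones. With the title-number term these were 17 and 10 for brush border and junction genes and 20 and 10 for fatty acid oxidation genes. All 26 fatty acid oxidation genes lay above 0 in HC569-A8-18, and the list was higher there (median 0.53, adjusted p = 5.79e-09, 0.278 with an estimated correlation). Pck1 stood at 65.0 CPM in HC800-A8-1 DOX and 0.156 CPM in HC569-A8-18 DOX libraries, Cabp2 at 122 and 1.67, Minar1 at 128 and 10.8, and Mettl7b at 11.9 and 35.5 (n = 2 per clone). In HC800-A8-1 759 genes were higher and 527 lower, and in HC569-A8-18 211 and 44. No library is shared between these 2 comparisons: 156 genes were higher in both (10.3 if independent, Fisher p = 4.29e-162), 32 lower in both (1.49 if independent, p = 5.02e-38) and 0 opposite (2.14 if independent). Both comparisons use the same estimate of spread for each gene, which favours calls of the same genes in both clones. The expected numbers and Fisher p values are therefore not valid measures of chance. The log2 fold changes of 11981 genes correlated with r = 0.70 (rank correlation 0.52), although genes are not independent. With the title-number term the clones had 5792 and 2162 calls, and in the 15783 libraries 5815 and 5886. Each HC800-A8-1 arm is 1 library there, so its spread is taken from the closer HC569-A8-18 replicates, and HC800-A8-1 fitted alone gave 0 calls (1863 unadjusted). HC800-A8-1 had 407 calls without its DOX replicate 1, 211 to 301 without 1 HC569-A8-18 library and 3222 without its control replicate 2. HC569-A8-18 had 0 calls without its control replicate 1, control replicate 2 or DOX replicate 2, 9 without its DOX replicate 1, and 619 and 616 without HC800-A8-1 control replicates 1 and 2.

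**Figure D3:**
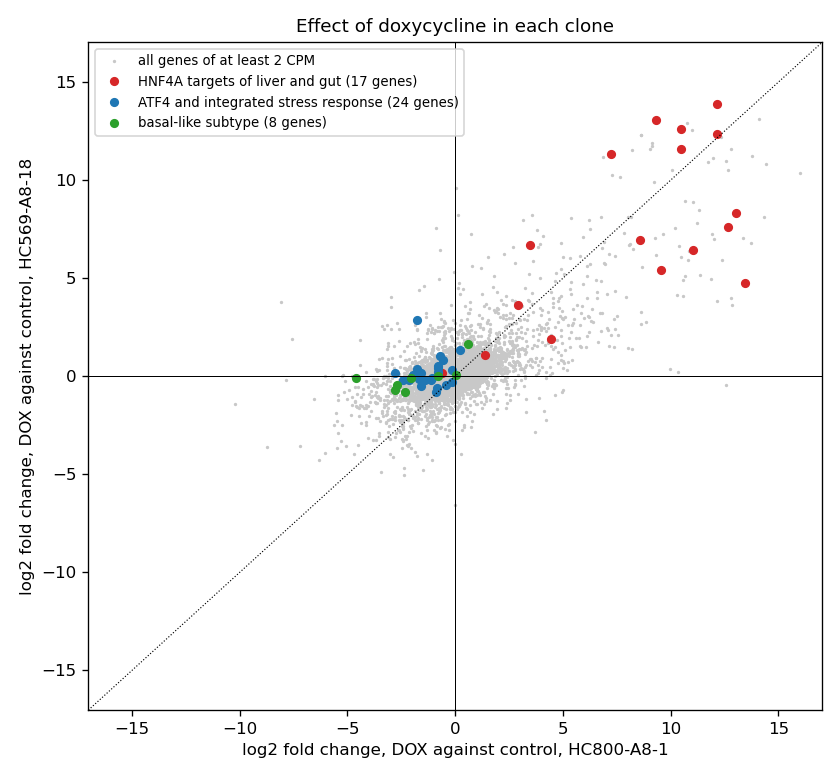
Log2 fold change with DOX in HC800-A8-1 and HC569-A8-18, with genes of 3 lists coloured.

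The difference between clones asked which genes answered DOX unequally. In the test with the title-number term, Anpep, a brush border peptidase gene, went from 0 to 35.5 ± 18.8 CPM in HC800-A8-1 and from 20.3 ± 5.75 to 15.0 ± 1.30 CPM in HC569-A8-18 (mean ± SD, n = 2, adjusted p = 0.00284). The acyltransferase gene Acnat1 went from 0 to 43.5 CPM and from 0.536 to 6.64 CPM (adjusted p = 0.00474). The complement protease gene Masp1 went from 14.9 to 7.93 CPM and from 0.194 to 37.9 CPM (adjusted p = 0.00196). The collagenase gene Mmp13 went from 258 ± 258 to 1.32 CPM in HC800-A8-1, and from 0.269 to 0.97 CPM in HC569-A8-18 (adjusted p = 0.0333). Without the term, Anpep had an adjusted p = 0.0622, Acnat1 0.0548, Masp1 0.0548 and Mmp13 0.167, and 0 genes passed with edgeR (1395 unadjusted, 449 with DESeq2). With the term 562 genes passed with a higher and 372 with a lower response in HC569-A8-18, in the 15783 libraries, with 1 library in each HC800-A8-1 arm and all spread from HC569-A8-18, 2616 passed, and without HC800-A8-1 control replicate 2 532. By list, some differences passed camera at the preset correlation. Those with a more positive response in HC569-A8-18 were basal-like genes (adjusted p = 6.08e-05, 0.397 with an estimated correlation), mesenchymal genes (0.00175, 0.808) and ATF4 genes (1.10e-05, 0.808). Over both clones neither the ATF4 nor the mesenchymal list passed without HC800-A8-1 control replicate 1 (0.927 and 0.0933), and this difference was not tested without it. Those with a more positive response in HC800-A8-1 were epithelial junction and brush border genes (camera adjusted p = 0.000143, 0.631) and fatty acid oxidation genes (0.00541, 0.808). With an estimated correlation none of these list differences passed, so an unequal response of the lists is not established.

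The control libraries of the clones asked how far the clones differ without DOX. The genes named by the rule as higher in HC569-A8-18 control libraries were all at 0 in HC800-A8-1 control libraries. These were the trefoil factor gene Tff1 (1301 ± 458 CPM, mean ± SD, n = 2, at least 18170.4-fold, adjusted p = 0.00134) and the mucin gene Muc5ac (393 ± 95.8 CPM, at least 5512-fold, 0.000688). They further included the mucin glycosyltransferase gene Gcnt3 (230.2 ± 35.1 CPM, at least 3245-fold, 0.000688) and the gastrokine gene Gkn2 (82.5 ± 37.9 CPM, at least 1147-fold, 0.00294). The kinase gene Lrrk2 (226 ± 94.3 CPM in HC800-A8-1) and the RNA-binding protein gene Khdrbs3 (225 ± 49.8 CPM) had 1 count each in HC569-A8-18. The ratios were 9.88e-05 (95% counting interval 2.50e-06 to 0.000551, adjusted p = 0.000922) and 9.79e-05 (2.48e-06 to 0.000546, 0.000634). The glypican gene Gpc4 (79.6 ± 84.8 CPM) and the ion channel gene Piezo2 (57.6 ± 64.6 CPM) were at 0 in HC569-A8-18, at least 1324-fold (adjusted p = 0.0132) and 811-fold (0.0239) lower. Hnf4a was log2 1.89 (SE 0.50, adjusted p = 0.0425) higher in HC569-A8-18. In all, 1681 genes were higher and 1616 lower in HC569-A8-18 (edgeR, Benjamini-Hochberg), with 6719 genes passing with the title-number term, 9364 in the 15783 libraries, 570 to 1467 without 1 HC569-A8-18 library and 5753 without HC800-A8-1 control replicate 2. In lists tested after these counts were seen, classical subtype genes were higher (11 higher and 1 lower, adjusted p = 2.08e-06, 0.550 with an estimated correlation) and mesenchymal genes lower (1 and 11, 0.000640, 0.708). Gpc4 did not pass without either HC569-A8-18 control library (0.0688 to 0.0757) and Piezo2 without those or either HC800-A8-1 DOX library (0.0523 to 0.112). Neither passed with no filter on low counts (0.0910 and 0.196).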

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

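The tests of the patterns below were chosen after the results were seen, except that of Hnf4a activity in control cells, and they are tests, not predictions. Libraries apart from the other 3 of their arm were sought with Dixon's ratio of gap to range, which flagged 14 of 114 sets of values. The 5.7 expected by chance assume exchangeable libraries and independent sets. Each arm mixes 2 clones, the sets share libraries, and every flag fell on an HC800-A8-1 library. The number 5.7 is therefore not a valid expectation here, and some flagged gaps are small. Rn7sk, a small nuclear RNA, stood apart in the HC800-A8-1 replicate 1 libraries (386885 counts in control, ratio 0.999821, and 241039 in DOX, ratio 0.99992). The same HC800-A8-1 control replicate 1 library stood apart for the histone gene Hist1h1c (579 CPM against 47.2 to 50.7, ratio 0.971), mt-Cytb (153 against 4179.8 to 5011, 0.948), mt-Co1 (4981 against 9557 to 10733, 0.849), Hadh (48.7 against 94.0 to 98.7, 0.931) and Atf4 (867 against 278 to 315, 0.891). HC800-A8-1 DOX replicate 1 stood apart for mt-Cytb (593 CPM against 4681 to 6651, 0.855) and Cyp4f14 (6.38 against 26.9 to 34.5, 0.853). HC800-A8-1 DOX replicate 2 stood apart for Hadh (264 CPM against 193 to 200.1, 0.883), Atf4 (263.7 against 277 to 279, 0.877), Spp1 (2450.3 against 947 to 1065, 0.877), Six1 (4.70 against 1.18 to 1.42, 0.868) and the mitochondrially encoded share of counts (3.11%, 95% Wilson interval 3.10 to 3.11, against 2.23 to 2.37%, ratio 0.841).

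The DOX effect on several genes was unequal between the clones with the title-number term (log2, HC569-A8-18 minus HC800-A8-1, adjusted p under the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hnf4a differed by −3.17 (SE 0.40, adjusted p = 0.0112; −2.98, SE 0.69, adjusted p = 0.257 without the term) and the villin gene Vil1 by −4.67 (adjusted p = 0.0115). Padi4 (3.68, adjusted p = 0.0451), Mcpt8 (2.01, 0.0456), Nes (1.40, 0.0249) and Pcsk9 (2.88, 0.0110) fell further in HC800-A8-1, and Fbln1 differed by 2.21 (0.00696). The largest positive differences were those of the imprinted RNA gene Rian (11.57), Mmp13 (8.92), Lilr4b (8.58), Masp1 (8.39), Akap12 (7.31) and Ddah1 (6.78). The largest negative ones were those of Anpep (−13.04), Ggt1 (−10.02), Kdf1 (−9.51), Acnat1 (−9.24), Ifi27l2b (−8.81) and Lcp1 (−8.29), all 6 at 0 in HC800-A8-1 control libraries, so the fitted sizes rest on genes near 0 and only their sign and CPM carry information. Rian went from 28.7 ± 32.5 to 0.101 CPM in HC800-A8-1 and Lilr4b from 36.7 ± 46.6 to 0.0295 CPM (mean ± SD, n = 2), so the control replicates themselves were far apart. With the term 934 genes passed. By list, the difference passed for basal-like genes (adjusted p = 6.08e-05), epithelial junction and brush border genes (0.000143), mesenchymal genes (0.00175), fatty acid oxidation and uptake (0.00541), cholesterol synthesis (0.0326) and ATF4 genes (1.10e-05), and for cytosolic ribosomal proteins with the term (0.0139). None of these lists passed with an estimated correlation.

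The HC800-A8-1 replicate 1 libraries held more histone, small nuclear and Rn7sk transcripts than replicate 2 of the same clone. The histone median was higher by log2 7.00 in control and 6.20 in DOX libraries (HC569-A8-18: 0.17 and −0.04). A preparation that kept RNAs without a poly(A) tail in the 15145 libraries, but not in the 15783 libraries, would give this. The labels give 1 kit and removal of ribosomal RNA for all, which does not select for a poly(A) tail. On that reading the 15783 libraries, not the 15145 libraries, depart from the labels. Depth was excluded, since the median was still 6.01 after every library was thinned to the lowest total. For other protein-coding genes the log2 differences between these replicates had an SD of 0.893 or more (HC569-A8-18: 0.297 and 0.215), which a uniform loss of counts to such RNAs would not produce.

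Fewer genes passed in HC569-A8-18 than in HC800-A8-1, yet the HC569-A8-18 replicates lay closer together. Fitted alone, HC569-A8-18 had 5850 calls and HC800-A8-1 0, so the order of the clones depends on the estimate of spread. Spread that the 15145 libraries add to the shared estimate is a possible cause. That estimate serves both clones, so a rise in calls without these libraries cannot decide it. A smaller DOX effect was left undecided: the lower HC800-A8-1 pair had 1.35 times as many genes at least 4-fold apart as the higher HC569-A8-18 pair (pairs 1192 and 663 against 490 and 444 genes), and these causes cannot be told apart here.

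Hnf4a transcript was present in HC569-A8-18 control libraries at 134 and 141 CPM. RNA of DOX-treated cells in these libraries was excluded as the source, because 54.5% of the 211 genes higher with DOX in HC569-A8-18 had a control share whose upper limit lay below the 12.6% of Hnf4a. Whether that transcript is active was left undecided. The 211 genes had a median control difference between clones of 0, at percentile 60.3 of matched random lists (0.17, at percentile 99.7, with the title-number term). They were chosen as higher with DOX than in the same HC569-A8-18 control libraries, which favours low control values in that clone. The matched lists carry no such choice, so the comparison is tilted against finding activity.

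The grouping itself was compared with the other even splits of the 8 libraries. The real split was the only 1 of 34 with as many higher genes (858, against at most 3) and with as many lower genes (375, against at most 7). For gene lists at the preset correlation 14 of 34 splits called as many as the real 13, up to 17 in a split that put both 15145 libraries on 1 side, so that count does not stand apart from other groupings. With an estimated correlation the real split alone (1 of 34) called 4 lists, HNF4A targets, classical subtype, epithelial junction and brush border, and xenobiotic metabolism, against 0 in any other. The other splits put DOX and control libraries on the same side, so the DOX effect enters their spread. This lowers gene calls and can raise the estimated correlation of genes that move together. The low counts there were largely set by the design and do not weigh the real split against chance.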

How the results depend on the processing

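The title-number term, the 15783 libraries alone and leaving out each library were chosen after the data had been seen; they are tests, not predictions. Named genes and lists that passed over both clones kept their direction, except the ATF4 list, which reversed without HC800-A8-1 control replicate 1 (adjusted p = 0.927, against 0.00137 without HC800-A8-1 control replicate 2; the cause was not tested). Among those that had not passed, some changed direction under 1 or more settings, such as Cdh1, Hist1h1c and the endodermal, fibroblast, glycolysis and histone lists. Calls grew where the 15145 libraries were modelled or removed: higher genes of both clones from 858 to 1955 with the term and 2140 within 15783, lower genes from 375 to 1556 and 1813, HC800-A8-1 from 1286 to 5792 and 5815, HC569-A8-18 from 255 to 2162 and 5886, the difference between clones from 0 to 934 and 2616, and the control clones from 3297 to 6719 and 9364. Within 15783 each HC800-A8-1 arm is 1 library, so the spread there comes from HC569-A8-18. The term takes the mean gap between the HC800-A8-1 replicates out of the spread, so more calls with it do not show that it corrects a batch. DESeq2 gave 1579 higher, 1207 lower, 2911 in HC800-A8-1, 1072 in HC569-A8-18 and 449 for the difference. Without the clone term 157 higher and 22 lower genes were left, as the clones' own difference then enters the spread, and the mean of clone effects gave 591 lower genes. With no filter HC569-A8-18 had 672 calls, the difference 224, and Hnf4a stood at 4.46 with adjusted p = 0.0645 (edgeR, Benjamini-Hochberg; the cause was not tested). Each clone fitted alone gave 0 calls in HC800-A8-1 (1863 unadjusted) and 5850 in HC569-A8-18. Replicate numbers were not taken to pair the libraries: deviations of the same number correlated by 0.70 in HC800-A8-1, where the number coincides with the title number, and by −0.005 in HC569-A8-18. A replicate block gave 608 lower genes, 3836 in HC800-A8-1, 1077 in HC569-A8-18 and 168 for the difference, took the call from Six4 (adjusted p = 0.0584) and moved no other list call or gene call over both clones. Leaving out 1 library gave 291 to 905 higher, 103 to 517 lower, 211 to 3222 in HC800-A8-1, 0 to 619 in HC569-A8-18, 0 to 532 for the difference and 570 to 5753 for the control clones, and Hnf4a at 3.79 to 4.97. Where this leaves an arm with 1 library, that lone library is assumed to vary like the others. Of 24 lists 13 passed at the preset correlation and 4 with an estimated one. A filter of 1 CPM in 4 libraries took the call from coagulation (adjusted p = 0.319), mesenchymal (0.0544) and ribosomal lists (0.0544) and gave it to interferon (0.0413), with fewer genes tested; interferon also passed with no filter (0.0228) and no clone term (0.0364). Of 57 named genes other than Hnf4a that passed over both clones, 57 passed with the term and within 15783, 55 with DESeq2 (not Krt5, 0.0515, or F10, 0.0595), 54 with the mean of clone effects (not Mmp10, 0.123, Krt5, 0.167, or F10, 0.99996), 52 with no filter (not Pck1, Slc27a2, Pcdh9, Krt5 or Pcsk9, 0.0562 to 0.133), 21 without the clone term and 38 to 56 with 1 library left out. Small effects can be missed: on data simulated at the depth and spread of these libraries the comparison over both clones recovered 25% of genes changed by log2 1, and the difference between clones 0%.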

Other observations

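The families below were grouped by shared gene-symbol stems after the data had been seen, and the chromosome test was set after the control medians, but before the DOX medians, had been seen. These are tests, not predictions. Among 246 stems of at least 8 tested genes, higher calls with DOX were concentrated in families of liver and gut detoxification: Cyp2 cytochromes (8 of 17 genes, adjusted p = 0.000246), Ces carboxylesterases (6 of 9, 0.000246), Ugt glucuronosyltransferases (5 of 10, 0.00493), Cyp4 cytochromes (4 of 8, 0.0220) and Abcc transporters (4 of 9, 0.0324). Serpinb protease inhibitors (6 of 14, 0.00381) and genes with the Abhd stem (7 of 20, 0.00381) were also concentrated. The Abhd stem is that of hydrolases, but the called genes include Abhd11os, which shares only the symbol stem. Neither family had a list fixed beforehand, although Serpinb3a was in the basal-like list. Serpinb1a, an inhibitor of neutrophil proteases, rose from 3.94 to 84.6 ± 35.0 CPM (mean ± SD, n = 4, log2 4.45, SE 0.51, adjusted p = 0.00449, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Abhd2 rose from 224 to 477 CPM (log2 1.09, SE 0.18, adjusted p = 0.0135). Ces2c rose from 0.21 to 63.5 ± 24.2 CPM (adjusted p = 0.00336) and Ugt2b34 from 16.7 to 158 ± 101 CPM (0.00143). Lower calls were concentrated in Mmp metalloproteinases (Mmp3, Mmp10, Mmp11 and Mmp17 of 13, adjusted p = 0.0490), but not with the title-number term. In that fit lower calls were concentrated in Nup nucleoporins (10 of 20, adjusted p = 0.00171), and higher calls further in Tmem (42 of 182, 0.00350), Coq (6 of 11, 0.0279) and Hsd genes (6 of 11, 0.0279). Mmp11 fell from 22.7 ± 4.79 to 7.82 ± 3.30 CPM (log2 −1.59, SE 0.35, adjusted p = 0.0361). The named genes were chosen after their values were seen, and which member of a family a read came from is uncertain.

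Whole chromosomes differed between the clones in their control libraries. The median log2 difference (HC569-A8-18 minus HC800-A8-1) was 0.70 over 420 genes of chromosome 14, 0.61 over 425 genes of chromosome 19, 0.60 over 564 genes of chromosome 10, −0.52 over 363 genes of chromosome X and −0.50 over 684 genes of chromosome 9. The hypothesis was a difference in copy number of whole chromosomes, under which the DOX libraries of the same clones should differ alike. Their medians were 0.67, 0.56, 0.65, −0.43 and −0.46 in the same order, the smallest in the direction of the controls being 0.433. Any lasting difference between the clones would repeat in this way, so the test leaves copy number undecided. In the 15783 libraries the control medians were 0.75, 0.56, 0.62, −0.54 and −0.46. The DOX effect itself moved no chromosome median by more than 0.14, and control and DOX medians of 20 chromosomes correlated with r = 0.98. Of these 20, 18 passed a permutation test after adjustment, the smallest p of 1e-04 being the smallest the permutations can give. Xist, the RNA of the inactive X chromosome, stood at 1457 to 2241 CPM in HC569-A8-18 and 229.5 to 755 CPM in HC800-A8-1 libraries. No DNA was measured, and 1 clone per tumor line cannot speak for the lines.

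No library of doxycycline-treated cells without the introduced Hnf4a was analysed here, so effects of the drug itself cannot be separated from those of Hnf4a.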
